A study of Arabidopsis thaliana with 12 samples.

How the data were processed

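The series measured N6-methyladenosine (m6A) and transcript levels in the aerial part of 3-week-old Arabidopsis thaliana. The reference accession Col-0 was set against a mettl16 mutant. There were 12 samples in 4 groups of 3 biological replicates, namely m6A immunoprecipitates and RNA-seq libraries of each genotype. Per the labels' protocols, plants grew in long days of 16 h light and 8 h dark at 23 °C. Polyadenylated RNA was cut into pieces of about 100 nt and a portion was enriched with an antibody against m6A. Enriched and untreated (input) RNA became strand-marked libraries that were read as 150 bp pairs.

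Expression was taken from the authors' deposited FPKM values (fragments per gene scaled by transcript length and library size) for the 6 RNA-seq (input) libraries. Col-0 and mettl16 columns were matched to samples by genotype and replicate number. The m6A comparison was taken from a table deposited by the authors with a row for each peak, in which 9 rows repeat an interval; peak counts are counts of rows unless repeats are said to be counted once. Per the file headers, it gives a log2 fold change, a p-value of the difference, the log10 of its FDR (a score below 0) and a p-value of the peak itself. The direction of the fold, mettl16 over Col-0, was read from the order in which the table names the genotypes. The submitters' processing notes name cutadapt, fastp, HISAT2, StringTie, HOMER and edgeR and the genome build TAIR10, with no versions or roles. The peak caller, the definition of the fold, the way replicates entered the comparison and whether strand was used in counting are not given in the sources used here. Coordinates are those of the authors' files, counted from 1. Gene symbols came from the RefSeq gene table of assembly TAIR10.1, which held 95.5% of the expression identifiers and 98.7% of the genes with a peak.

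Sequencing depth is not stored in FPKM. The lowest values gave a rough relative depth of 0.64 for Col-0 replicate 1, 0.927 and 1 for the other Col-0 libraries, and 0.946, 0.945 and 0.829 for mettl16. Estimates were not whole fragments, so no count was recovered. 6 genes (SLP2, bZIP2, AT4G34588, AT5G50650, SPL13B and SAE1B) were at 0 in some libraries of a genotype and at or above 5 FPKM in another library of it, so a 0 can be a failed estimate and such genes are called listed at 0.

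For expression, genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1), with the pseudocount of 1. The test was limma 3.58.1 in R 4.3.3, with a trended and robust prior variance, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. A fold change is therefore on the log2(FPKM + 1) scale and understates the change of genes with low values. On data simulated for this comparison over 19505 genes, the test recovered 40% of genes changed by 0.25 on the log2 scale, 78% at 0.5, 94% at 1 and 100% at 2, with 50 genes each, and made 6 false calls. That simulation changed far fewer genes than the 12584 called in the real comparison, so its adjusted threshold was stricter. Its recovery and false calls therefore do not describe the real comparison. The series design states Col-0 as the reference. Replicate numbers do not mark a shared batch in the labels and were not used as a block. The test was chosen for FPKM, so the count-based tests planned in case of counts were not used.

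Gene lists were fixed before the data were examined: floral repressors, floral activators, floral meristem and organ identity, the autonomous flowering pathway, m6A machinery, the circadian clock, the methionine and S-adenosylmethionine cycle, light harvesting and Rubisco, salicylic acid defence, cold and abscisic acid response, leaf senescence, gibberellin, photomorphogenesis, SR splicing factors, anther and pollen markers, root markers and reference genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists with tested members, again with an estimated correlation, and with fry. Member counts are given over all genes tested and adjusted over the list alone. Pathways were those of the KEGG annotation in the authors' file, with at least 10 tested genes. Lists of mitochondrial stress and cytosolic heat-shock genes were added after the strongest changes had been seen.

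Peaks were called different at the authors' FDR under 0.05. Position classes were compared between higher and lower peaks with Fisher's exact test. The peak change, averaged over the peaks of a gene, was set against the expression change with Spearman's rho and Pearson's r and 100000 permutations over genes, two-sided. Overlaps of called genes were tested with Fisher's exact test among genes with both values. A gene had lower m6A when it had a lower and no higher peak, and the reverse for higher m6A. On simulated values for 5681 genes with a true r of -0.2 the estimate was -0.206. These steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

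Genes were named by a rule fixed before the data were examined. FIO1 came first, then FLC, SOC1 and FT, up to 4 called members of each list with the largest absolute change, and the 10 largest increases and decreases whose libraries did not overlap and whose higher genotype had at least 1 FPKM. Peaks named were the 8 largest increases and decreases past the threshold, up to 4 called peaks in each list, and all of FLC, SOC1, FT, SPL3 and SEP3. Other list members and the neighbours of FIO1 are named as examples after their values were seen. Alternatives chosen before the data were examined were pseudocounts of 0.1 and 0.01, no filter and a filter of 2 FPKM, median centring, quantile normalization, rescaling to TPM, a constant prior variance, a replicate block, leaving out each library, stricter thresholds of 0.01, an absolute log2 fold change of at least 1, and other ways of choosing peaks and genes. Motif analysis was not done, since no genome sequence was used here.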

Results

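Transcript levels and m6A were compared between Col-0 and a mettl16 mutant in the aerial part of 3-week-old plants, in a study of the role of m6A in the floral transition. The mutant is named after METTL16, an m6A methyltransferase; FIO1, its Arabidopsis homologue, was taken to be the mutated gene from general knowledge, since the labels give no locus. Each genotype had 3 RNA-seq libraries and 3 m6A immunoprecipitates. The expression table held 25566 genes, of which 19505 were tested. FPKM values summed to between 714685 and 718824 in the Col-0 libraries and between 699031 and 706690 in the mettl16 libraries. Pearson's r of log2 values lay between 0.994 and 0.996 within a genotype and between 0.957 and 0.959 across genotypes. Col-0 replicate 1 was the shallowest library and listed 3120 genes at 0, against 1939 to 2622 in the other libraries.

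FIO1 (AT2G21070; chromosome 2, 9040852 to 9043626, build TAIR10) was measured at 1.98, 2.13 and 2.31 FPKM in the Col-0 libraries and at 0.292, 0.148 and 0.197 FPKM in the mettl16 libraries. It fell by 1.37 on the log2(FPKM + 1) scale (SE 0.0853, limma adjusted p = 4.94e-07). Nearby, GRP2B, LAX2, AT2G21090 and AT2G21130 rose by 0.29, 0.64, 0.43 and 0.95 (adjusted p = 0.0212, 6.54e-07, 0.00292 and 8.14e-06), and AT2G21080, SYTA and AT2G21120 did not pass the test (adjusted p = 0.865, 0.595 and 0.399).

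The question of the expression comparison was which transcripts differ between the genotypes around flowering. In mettl16, 11 of 16 floral repressors fell, 13 of 16 floral activators and 11 of 11 floral meristem and organ identity genes rose, and 17 of 18 antenna genes but 1 of 4 Rubisco small-subunit genes, 14 of 16 salicylic acid defence genes and 9 of 11 leaf senescence genes fell. The 6 lists these come from passed camera with the preset correlation and none passed with an estimated one (adjusted p = 0.0546 to 0.123 with an estimated correlation). limma called 12584 genes, 8016 higher and 4568 lower in mettl16. With an absolute log2 change of at least 1 there were 590 higher and 397 lower genes. The 3 values of one genotype lay wholly above those of the other in 69.8% of tested genes, where chance gives 10%. The share of called genes that were higher was 63.7% with FPKM as deposited, 52.5% after median centring and 49.3% after quantile normalization. The median log2 change of all tested genes was 0.08, so small rises are read against that shift. Counts of risers and fallers in a list are read against 8016 and 4568 of the 19505 tested genes. The 11 floral identity genes are those of 17 members that reached the filter, which favours risers among genes near 0 in Col-0.

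Floral repressors fell as a group. Of 16 tested members 11 fell and 1 rose, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.44e-06; adjusted p = 0.0546 with an estimated correlation). FLC (AT5G10140), the MADS-box repressor behind the vernalization requirement, went from 2.84 ± 0.474 to 0.0378 ± 0.0406 FPKM (SD, n = 3 each), a log2 change of -1.88 (SE 0.102, adjusted p = 1.9e-07). TEM2, a repressor of FT, fell from 32.8 ± 0.451 to 6.18 ± 0.247 FPKM, a log2 change of -2.24 (adjusted p = 2.03e-10). MAF4, a close relative of FLC, fell by 1.57 to 0.551 ± 0.127 FPKM (adjusted p = 5.81e-07). SVP and FLM, whose products repress flowering together, changed by -0.74 and -0.82. TFL1, which keeps the shoot apex indeterminate, was the member that rose, from 0.697 ± 0.132 to 3.49 ± 0.385 FPKM (adjusted p = 7.44e-07). MAF2 (adjusted p = 0.347), MAF3 (0.0563), SMZ (0.448) and FRI (0.581) did not pass the test.

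Floral activators rose in 13 of 16 tested members and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00102; adjusted p = 0.0613 with an estimated correlation). FT (AT1G65480), the mobile flowering signal, went from 0.789 ± 0.0763 to 14.7 ± 0.336 FPKM, a log2 change of 3.13 (SE 0.0601, adjusted p = 2.35e-10). SOC1 (AT2G45660), a MADS-box integrator, went from 20.4 ± 0.965 to 35.0 ± 0.926 FPKM, a log2 change of 0.75 (adjusted p = 2.09e-07). FUL rose by 1.87, SPL15 by 1.17 and SPL3, a target of miR156, by 1.15. GI, a clock-linked promoter of flowering, was the member that fell, by 0.17 (adjusted p = 0.0319), and with FPKM rescaled to TPM no member fell.

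Floral meristem and organ identity genes rose in all 11 tested members, also adjusted over the list alone (camera adjusted p = 4.18e-06, or 0.0546 with an estimated correlation). Of 17 members 11 reached the filter on the mean of the 6 libraries. A member near 0 in Col-0 could reach it only by being higher in mettl16. The count of risers and the camera result are therefore partly fixed by the filter. SEP3 rose from 0.216 ± 0.0918 to 22.4 ± 0.619 FPKM, a log2 change of 4.27 (adjusted p = 8.42e-11). AP3 and PI, which specify petals and stamens, rose by 3.41 and 3.13, and AP1, which specifies the floral meristem, by 3.34. Anther and pollen markers rose in 5 of 6 tested members (camera adjusted p = 0.0138, or 0.251 with an estimated correlation), also 5 adjusted over the list alone. That list has 11 members, and the same limit of the filter holds for it. AMS, a tapetum regulator, rose by 1.32. A9 was listed at 0 in the 3 Col-0 libraries and at 3.52, 4.49 and 5.18 FPKM in mettl16. A6 was listed at 0 in Col-0 and at 3.11, 3.09 and 3.42 FPKM in mettl16, and ATA7 at 0 and at 3.10, 2.39 and 2.49 FPKM. The mettl16 libraries thus carried floral organ and anther transcripts that were near 0 in Col-0, and this difference goes with each group described here. Root markers had 6 of 10 members in the table and none reached the filter for testing.

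**Figure D1:**
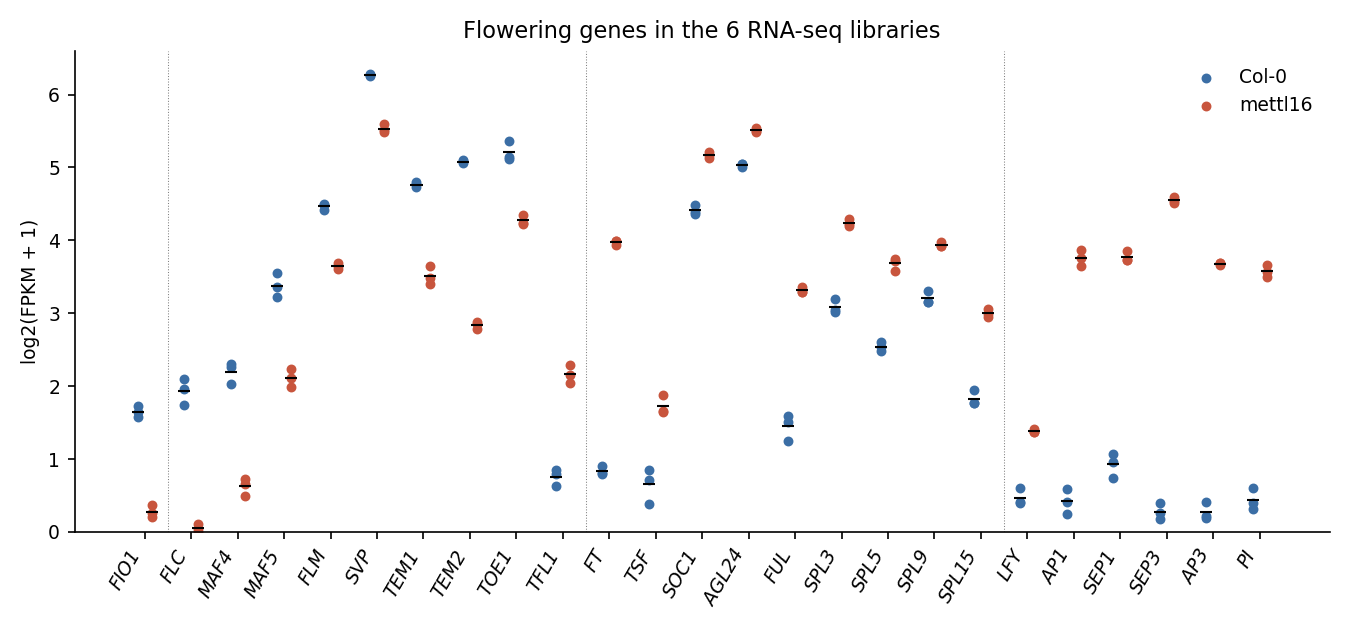
Each point is 1 RNA-seq library of Col-0 (blue) or mettl16 (red), each black line the mean of 3 libraries, and the vertical axis is log2(FPKM + 1). FIO1 stands first, then selected floral repressors, floral activators and floral identity genes, separated by dotted lines. Members not shown include GI, the activator that fell, and MAF2, MAF3, SMZ and FRI, repressors that did not pass the test. FT rose from 0.789 to 14.7 FPKM and FLC fell from 2.84 to 0.0378 FPKM.

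The m6A machinery list had 7 members that rose and 1 that fell, FIO1, of 12 tested (camera adjusted p = 0.203), with the same counts adjusted over the list alone. ALKBH9B, an m6A demethylase, rose from 5.37 ± 0.218 to 10.2 ± 0.859 FPKM, a log2 change of 0.81 (adjusted p = 2.79e-06). The m6A readers ECT3 and ECT2 rose by 0.76 and 0.57. MTB, FIP37, VIR and HAKAI of the main methyltransferase complex had log2 changes between -0.04 and 0.06 and did not pass the test, while MTA rose by 0.38. The autonomous pathway, which represses FLC, had 3 risers of 8 tested, also 3 adjusted over the list alone (camera adjusted p = 0.482). These were FLK (0.58), FVE (0.39) and FY (0.23).

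Light harvesting and Rubisco genes fell in 18 of 22 tested members and rose in 3, with the same counts adjusted over the list alone (camera adjusted p = 9.14e-11; adjusted p = 0.123 with an estimated correlation). The fall was in 17 of the 18 antenna (LHC) genes of the list, or 13 after quantile normalization. LHCB4.3 rose, though no antenna gene of the list did after median centring. The KEGG antenna pathway had 25 tested genes, of which 19 fell and 5 rose (camera adjusted p = 5.15e-08, or 0.303 with an estimated correlation). Of the 4 Rubisco small-subunit genes RBCS2B fell, RBCS1A (0.09, adjusted p = 0.0442) and RBCS1B rose, and RBCS3B did not pass the test (adjusted p = 0.598). In the whole list, after quantile normalization 14 fell and 3 rose, with the median going from -0.64 to -0.25, and after median centring 18 fell and 1 rose. LHCB1.4, a chlorophyll a/b-binding protein of photosystem II, fell from 1162 ± 41.5 to 113 ± 2.31 FPKM, a log2 change of -3.35 (adjusted p = 4.35e-12). LHCB2.3, LHCB1.2 and RBCS2B fell by 1.76, 1.53 and 1.29. RBCS1B rose by 0.27, and both RBCS genes and the LHCB1 genes have near-identical copies, so the split of reads between copies is uncertain. The list held between 15.5% and 15.7% of all FPKM in the Col-0 libraries and between 11.2% and 11.8% in mettl16. In photomorphogenesis, 6 of 12 tested members fell and 4 rose, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.0571). PIF4, a light-signalling transcription factor, fell by 1.06, CRY1 by 0.71 and PIF1 by 0.58, and HYH rose by 0.87. In the circadian clock list 8 of 14 tested members rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.619). After quantile normalization 5 clock genes rose and 4 fell. LHY rose from 42.1 ± 4.04 to 90.3 ± 2.55 FPKM and CCA1 by 0.34, and PRR7 and CHE fell by 0.71 and 0.67.

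Salicylic acid defence genes fell in 14 of 16 tested members and none rose, also adjusted over the list alone (camera adjusted p = 2.01e-09; adjusted p = 0.0613 with an estimated correlation). PR2 fell from 83.1 ± 1.31 to 8.64 ± 0.256 FPKM, PR1 from 24.2 ± 1.34 to 3.93 ± 0.365 FPKM and PR5 from 45.3 ± 1.84 to 9.61 ± 0.623 FPKM (adjusted p = 1.26e-11, 1.99e-09 and 8.94e-10). PAD3, of camalexin synthesis, fell by 1.55. Leaf senescence genes fell in 9 of 11 tested members and none rose, also adjusted over the list alone (camera adjusted p = 4.17e-05; adjusted p = 0.0546 with an estimated correlation). SEN1 fell by 2.71, SAG13 by 1.74, NAP by 1.52 and SAG21 by 0.90. Cold and abscisic acid response genes rose in 4 and fell in 3 of 11 tested members, also adjusted over the list alone (camera adjusted p = 0.619). After median centring or quantile normalization the balance turned, with 3 risers and 6 fallers. KIN1 and RAB18 rose by 0.90 and 0.68 and COR15A fell by 0.41. CBF2 had a log2 change of -0.36 (adjusted p = 0.03), which was lost without Col-0 replicate 1 (0.0757) or 3 (0.076), without mettl16 replicate 1 (0.107) or 2 (0.108) and with no filter (0.0528), and lay between 0.00112 and 0.108 over the settings run. Gibberellin genes rose in 5 and fell in 4 of 13 tested members, also adjusted over the list alone (camera adjusted p = 0.579). After median centring 5 gibberellin genes rose and 6 fell, and after quantile normalization 5 and 7. GA2OX1 and GA2OX2, which inactivate gibberellin, rose by 0.98 and 0.66, RGL2, a DELLA repressor, by 0.66, and GA3OX1 of gibberellin synthesis fell by 0.68. In the cold and gibberellin lists the median log2 change was below 0 and the mean above 0.

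Methionine and S-adenosylmethionine cycle genes rose in 11 and fell in 2 of 16 tested members, also adjusted over the list alone (camera adjusted p = 0.0439; adjusted p = 0.212 with an estimated correlation). After quantile normalization 9 rose and 5 fell. The call was lost after median centring (0.0646) and without Col-0 replicate 1 (0.0635) or mettl16 replicate 2 (0.0523), and the adjusted p lay between 0.0373 and 0.0646 with the preset correlation. SAHH2, which clears S-adenosylhomocysteine, rose from 199 ± 3.16 to 396 ± 6.77 FPKM, HMT2 rose by 0.68, ADK1 (AT3G09820), an adenosine kinase, rose by 0.51 and HMT3 fell by 0.68. SR splicing factors rose in 17 and fell in 2 of 21 tested members, also adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.0988 with an estimated correlation). After median centring or quantile normalization 12 rose and 2 fell, with medians of 0.21 and 0.16 against 0.28. SCL30A rose by 0.59, SR45 by 0.53 and RSZ22 by 0.46. The list also counts the RNA-binding proteins GRP7, which rose by 0.58, and GRP8, which are not SR proteins. Reference genes rose in 5 and fell in 1 of 8 tested members, also adjusted over the list alone (camera adjusted p = 0.203), with GAPC2 at 0.50, EF1A at 0.48, ACT2 at 0.30 and PP2AA3 at 0.28. Those counts were the same under median centring, quantile normalization and TPM. Of the 16 lists, 9 passed with the preset correlation and none with the estimated one, where camera gave 6 an unadjusted p under 0.05. fry gave p-values between 5.9e-09 and 0.0228 for the 16 lists. It asks whether the members of a list changed, not whether they changed more than other genes. Of the 19505 tested genes 12584 were called, so a list can pass fry without standing out. The reference genes and the lists that camera did not call passed it too. The fry result therefore does not set any list apart and does not make up for the calls lost with an estimated correlation.

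**Figure D2:**
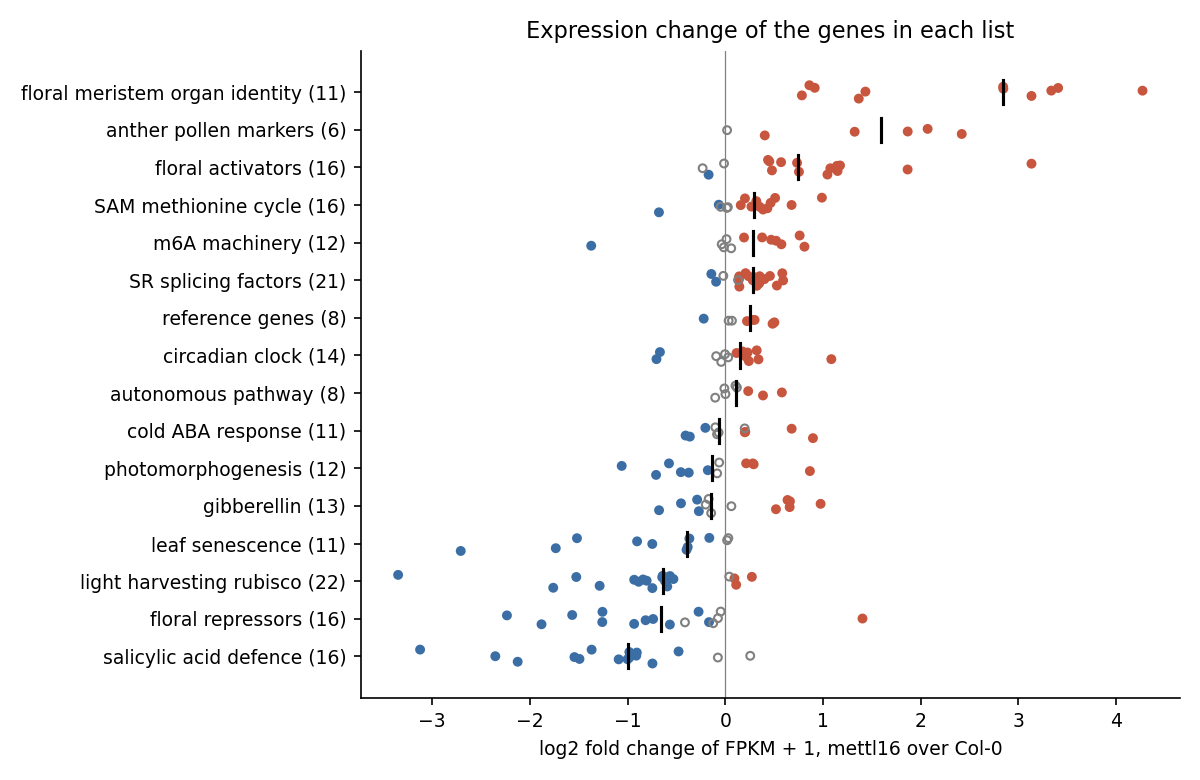
Each point is a tested gene, placed by its log2 fold change of FPKM + 1 (mettl16 over Col-0), with the number of tested genes beside each list. Filled red points rose, filled blue points fell, open points did not pass an adjusted p of 0.05, and black lines are medians, the highest at 2.84 for floral meristem and organ identity and the lowest at -0.99 for salicylic acid defence; with FPKM rescaled to TPM the highest was 1.94 for anther and pollen markers, against 1.65 for floral identity.

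The largest increases were those of AT5G22430, a pollen Ole e 1 family gene, from 0.106 ± 0.0730 to 59.0 ± 1.70 FPKM, and CYP96A15, an alkane hydroxylase of wax synthesis, from 0.278 ± 0.0656 to 59.7 ± 1.02 FPKM (log2 changes of 5.76 and 5.57). AT2G20870, annotated as a cell wall protein precursor, HSP23.5, a mitochondrial small heat-shock protein, and AT5G37940 rose by 5.28, 5.18 and 4.78. LTP4 and LTP3, a tandem pair of lipid transfer proteins that can share reads, rose by 4.66 and 3.64. PER64, SEP3 and RXF26 rose by 4.38, 4.27 and 4.18. The largest decreases were those of PDF1.2, a jasmonate-responsive defensin, from 20.6 ± 0.644 to 0.186 ± 0.0402 FPKM, LHCB1.4, and PORB, of chlorophyll synthesis, from 131 ± 0.761 to 13.9 ± 0.737 FPKM (log2 changes of -4.19, -3.35 and -3.15). PR2 and AT1G13470 changed by -3.12 and -2.92, AT1G15125 and AT3G55240 by -2.80 and -2.77, and AOC2, of jasmonate synthesis, by -2.71. AT1G27565 was measured at 5.84, 6.76 and 6.15 FPKM in Col-0 and listed at 0 in the 3 mettl16 libraries, and AT4G09310 at 5.91, 5.84 and 5.80 FPKM in Col-0 and at 0 in mettl16.

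The m6A comparison asked which methylated sites differ in the mutant. More peaks were lower than higher in mettl16, and the changes were mostly small. Of the 6437 peaks in the authors' deposited table, 4456 passed an FDR of 0.05, of which 3322 were lower and 1134 higher, or 74.6% lower. The median log2 fold change in the authors' deposited table was -0.30 among lower and 0.30 among higher peaks. Over all its peaks, called or not, the median was -0.227 and 71.5% were below 0. The share of lower peaks among called ones is thus near that of all peaks. The floral organ and anther transcripts that mettl16 carried and Col-0 nearly lacked go with each m6A difference described here, position classes included. Whether the common shift comes from scaling, from methylation or from such a difference in organs was not tested. At an absolute log2 fold change of at least 1, the authors' deposited table held 63 lower and 35 higher peaks. The FDR values of the authors' deposited table correspond to about 15300 tested peaks at low p and fewer at high p, so it holds part of the peaks compared. How replicates entered that comparison is not given in the sources used here.

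Among flowering genes, SEP3 had one of the largest decreases. Its 3' UTR peak (chromosome 1, 8593637 to 8594024, build TAIR10) had a log2 fold change of -2.36 (FDR 0.00724) in the authors' deposited table, while its transcript was at 0.216 FPKM in Col-0. MAF4 and FRI had lower 3' UTR peaks, by -0.80 (FDR 0.0012) and -0.78 (FDR 0.00759) in the authors' deposited table, and MAF5 a higher one, 0.33 (FDR 0.0105). SPL3 had 2 overlapping 5' UTR entries (chromosome 2, 14305001 to 14305565 and 14305008 to 14305542), at -0.25 (FDR 0.0115) and -0.24 (FDR 0.0229) in the authors' deposited table. SPL9 was at -0.28 (FDR 8.51e-05), SPL5 at 0.25 (FDR 0.000977), PI at 0.93 (FDR 0.0363) and SEP4 at -0.21 (FDR 0.0275) in the authors' deposited table. The PI transcript was at 0.365 FPKM in Col-0 and that of MAF4 at 0.551 FPKM in mettl16. As with SEP3, their folds rest on a low value in that genotype. The FLC peak (chromosome 5, 3175077 to 3175214, exon 4 of 7) had a log2 fold change of -0.41 and an FDR of 0.681 in the authors' deposited table. None of the peaks in the authors' deposited table was assigned to SOC1 or FT. FCA (-0.44, FDR 0.0269) and LD (-0.16, FDR 0.00174) of the autonomous pathway were lower in the authors' deposited table, and ECT2 was higher (0.16, FDR 0.00166).

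Clock genes with called peaks were all lower, namely ELF3 (-0.31), LHY (-0.14), CCA1 (-0.14) and PRR7 (-0.14) in the authors' deposited table. Of all 4456 called peaks, 3322 were lower, so this shared direction does not set the clock genes apart. The falls of LHY, CCA1 and PRR7 were smaller than the median over all peaks, -0.227, and that of ELF3 was larger. In light signalling, PHYA (0.46), CRY1 (0.20) and PIF4 (0.18) were higher and HYH (-0.22) and CDF1 (-0.18) lower in the authors' deposited table. Among antenna genes the authors' deposited table had LHCA2 (0.36) and LHCB4.1 (0.22) higher and LHCB3 (-0.25) and LHCB4.3 (-0.17) lower. In the splicing factor list RS41 (-0.32), SCL30A (-0.18), RS40 (-0.18) and the RNA-binding protein GRP7 (-0.19) were lower and SR34A (0.10) higher in the authors' deposited table. ICS1 was higher (0.28) and EDS5 (-0.15) and ERD10 (-0.32, FDR 1.58e-38) lower in the authors' deposited table. Of the reference genes, EF1A had 2 lower peaks, at -0.17 and -0.85, in the authors' deposited table. No list member of the S-adenosylmethionine cycle, leaf senescence, gibberellin, anther or root lists was among the peaks analysed here.

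Among the 8 largest decreases and increases, FLOT1, MC2, SAP130a and SEP3 lay above a mean of 1 FPKM, AT4G16267 had no FPKM value and the others lay below 1 FPKM. This mean is over both genotypes, and SEP3 was at 0.216 FPKM in Col-0 and 22.4 FPKM in mettl16. In the authors' deposited table the decreases were SAP130a (-5.92, chromosome 3, 20463442 to 20463719), AT4G16267 (-3.68), CHX21 (-3.62), AT4G01980.1 (-3.58), AT3G19310 (-2.88), SEP3, GRP20 (-2.25) and AT1G07710 (-2.24). SAP130a has a near-identical tandem copy, so its reads are uncertain, and the AT4G16267 peak lies in an annotated exon of AT4G16270. The increases in the authors' deposited table were AT5G36740 (4.62), AT4G02960.1 (4.40), AT1G71690 (2.57), FLOT1 (2.23), AT2G12440.1, AT5G34825.1 (2.13), AT1G68630 (2.13) and MC2 (2.11). Of the 98 called peaks with an absolute log2 change of at least 1 in the authors' deposited table, 45 lay in genes under 1 FPKM and 11 in genes of at least 10 FPKM. The SD of the log2 fold change in the authors' deposited table was 1.39 over peaks in genes under 1 FPKM and 0.286 over peaks in genes of at least 10 FPKM.

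Peaks in 3' UTRs made up most of both directions, and more so among higher peaks. In the authors' deposited table, 90.3% of the 1134 higher peaks and 78.6% of the 3322 lower peaks were in 3' UTRs (odds ratio 2.54, Fisher's exact adjusted p = 6.53e-20 over 3 classes). Peaks in 5' UTRs were 4.85% of higher and 9.69% of lower peaks in the authors' deposited table (odds ratio 0.475, adjusted p = 1.26e-07). Peaks in other exons were 4.85% and 11.7% (odds ratio 0.383, adjusted p = 2.31e-12) in the authors' deposited table. Among peaks with an absolute log2 change of at least 1 no class passed, with odds ratios of 1.01 for 3' UTRs, 3.76 for 5' UTRs and 0.833 for other exons.

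**Figure D3:**
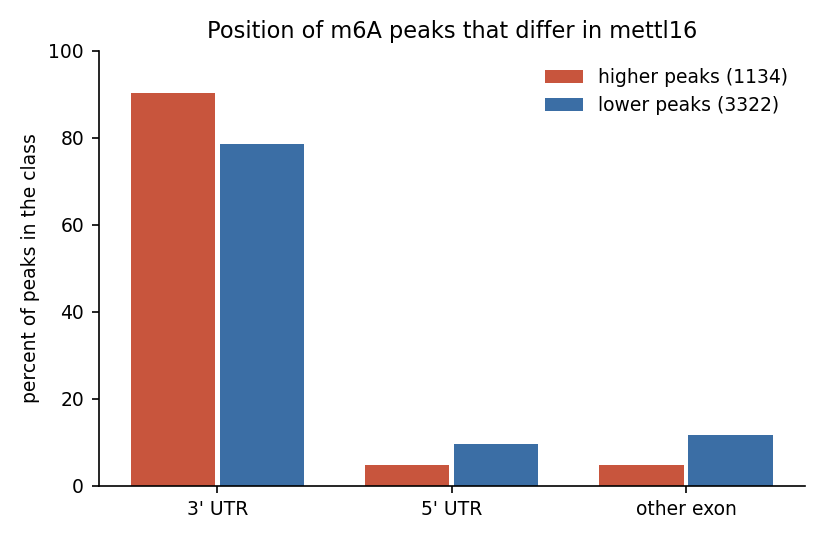
Bars give the percent of higher (red, 1134) and lower (blue, 3322) m6A peaks in each annotated position class, from the authors' deposited table. The 3' UTR holds 90.3% of higher and 78.6% of lower peaks.

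The last comparison asked whether m6A and transcript levels changed together. Genes with lower m6A more often rose in expression and genes with higher m6A more often fell. Over 5681 genes with both values, Spearman's rho across genes was -0.131 and Pearson's r -0.12. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and 1e-05 after adjustment for both. Genes are not independent replicates. Among 3038 genes with lower m6A, 1538 rose where 1359 were expected (odds ratio 1.68, Fisher's exact adjusted p = 1.78e-21) and 565 fell where 687.2 were expected (odds ratio 0.61, adjusted p = 9.73e-15). Among 1031 genes with higher m6A, 373 fell where 233.2 were expected (odds ratio 2.32, adjusted p = 1.16e-27) and 327 rose where 461.1 were expected (odds ratio 0.511, adjusted p = 8.06e-21). Examples in both sets were SPL3 and SPL9, lower in m6A and higher in transcript, and PHYA, CRY1 and PIF4, higher in m6A and lower in transcript. Of 30 list members called in both m6A and expression, 21 changed in opposite directions and 9 in the same. These 9 were SPL5, PI, ECT2 and SR34A, higher in both, and MAF4, PRR7, EDS5, LHCB3 and CDF1, lower in both. PI in Col-0 and MAF4 in mettl16 were below 1 FPKM. The same limit holds for SEP3, one of the 21, which was at 0.216 FPKM in Col-0. Over all genes called in both, 1538 and 373 changed in opposite directions and 565 and 327 in the same. The list members come from these genes and show a similar balance, so they are no separate support. The m6A values come from a partial table. The RNA-seq libraries are the input of the m6A samples, so both measures may share them, though the definition of the fold is not given.

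**Figure D4:**
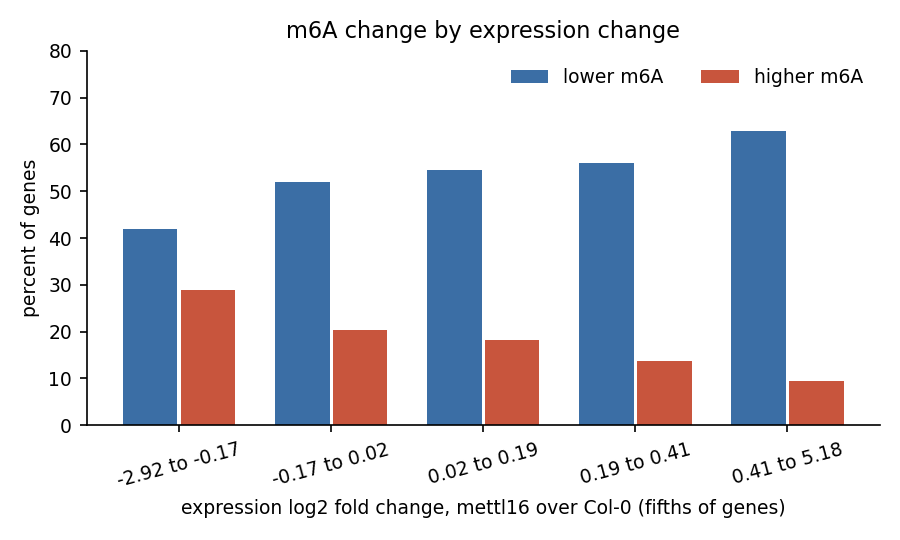
Genes with a peak were sorted by expression log2 fold change into 5 groups of 1135 to 1137 genes, labelled with their range on the horizontal axis, and bars give the percent of genes with lower (blue) and higher (red) m6A. Lower m6A went from 42.0% in the group with the strongest decreases to 62.8% in that with the strongest increases, and higher m6A from 28.8% to 9.42%.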

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

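Alternatives added after the data were examined left out genes listed at 0, required an absolute peak log2 change of at least log2 of 1.5, or counted repeated intervals once; the others were chosen before. The called gene counts stayed within 1.5 times of 8016 and 4568 under the pseudocounts, filters, scalings, prior and left-out zeros, and leaving out each library gave 7306 to 7749 higher and 4219 to 4277 lower genes. The fold threshold gave 590 and 397 genes by construction. After quantile normalization 49.3% of called genes were higher, against 63.7%. That scaling gives all libraries the same distribution and brought the median change to -0.00558. The balance of calls after it therefore follows from the scaling and does not test the excess of higher genes. The replicate numbers did not pair the samples: same-numbered libraries had correlations of deviations of -0.0823, 0.00866 and 0.00173. With a replicate block 7915 genes were higher and 4494 lower. Of the 81 genes named by the rule, 80 kept direction and call in the settings run, CBF2 being the exception, and none changed direction; other genes named as examples, such as GI, are not among them.

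With an estimated correlation camera called 0 lists higher and 0 lower, against 5 and 4, with 6 at an unadjusted p under 0.05. The estimate lay below the preset 0.01 for floral repressors (-0.0168), floral activators (-0.031), floral identity (-0.0688), leaf senescence (-0.065) and SR splicing factors (-0.00484). These estimates argue against a higher correlation of members as the reason for the lost calls in these lists. The p-values of these lists with an estimated correlation are therefore no evidence that their members are correlated. It was above 0.01 for light harvesting (0.326), anther markers (0.257), salicylic acid defence (0.146) and the methionine cycle (0.0228). The cause was not tested further. With a library left out, 4 to 5 were higher and 4 lower. Peak counts moved to 63 lower and 35 higher at an absolute log2 change of at least 1, and to 375 and 162 at log2 of 1.5, by construction. The odds ratios of 3' UTR and other exon classes, 1.01 and 0.833, no longer passed with peaks of at least 1, and that of 5' UTRs turned to 3.76, with 98 peaks left; the cause was not tested. DESeq2 was not run, since the values are FPKM. Library depth sets what low genes can show, and the depth behind each peak is unknown.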

Other observations

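The pathway tests and the mitochondrial, heat-shock and ribosome comparisons were chosen after the results they follow had been seen. Of 120 KEGG pathways, camera called 16 higher and 10 lower in mettl16, and none passed with an estimated correlation, where 18 had an unadjusted p under 0.05. Ribosome genes rose in 308 of 381 tested members (camera adjusted p = 2.93e-15; adjusted p = 0.251 with an estimated correlation), and ribosome biogenesis and DNA replication genes rose in 75 of 109 and 47 of 60. Glucosinolate biosynthesis genes fell in 15 of 22 and rose in 3 (adjusted p = 0.00044; 0.292 with an estimated correlation). The directions of these 4 groups held under median centring, quantile normalization and TPM.

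Ribosome genes were also prominent in the m6A comparison. Of 163 such genes with a peak, 141 had a lower and no higher peak in the authors' deposited table, where 84.09 were expected (odds ratio 6.25, Fisher's exact adjusted p = 1.91e-19 over 88 pathways). The median log2 fold change of their peaks in the authors' deposited table, -0.21, was no larger in size than that of other peaks, -0.23. Genes of plant-pathogen interaction were over-represented among genes with higher m6A, 29 of 79 where 14.07 were expected (odds ratio 2.72, adjusted p = 0.00326).

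27 genes were listed at 0 in the 3 Col-0 libraries and above 1 FPKM in the 3 mettl16 libraries. They included the tapetum and pollen coat genes LTP12 (9.40 to 10.1 FPKM), GRP17 (7.95, 7.64 and 7.63 FPKM) and GRP19 (8.72, 10.4 and 11.9 FPKM). The reverse held for 3 genes, AT1G27565, AT4G08093 and AT4G09310. These genes were chosen after their values were seen.

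Of the splits of the 6 libraries into 3 and 3, the real split called 12584 genes and the highest of the other splits 1. With 10 splits, the real one included, 1 called as many, and so few splits cannot give a share under 0.05.

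More genes were higher than lower in mettl16. A candidate explanation is composition: fewer reads on very abundant genes raise the FPKM of the rest. The 100 most abundant genes of Col-0 held 35.2% of FPKM there and 28.1% in mettl16, which alone would raise the share of all other genes by 0.15 on the log2 scale, against a median change of 0.118 with FPKM rescaled to TPM. After median centring 52.5% of called genes were higher, but centring itself brings the changes to about 0, so this does not decide between composition and a biological rise across many genes. Both remain open.

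The negative relation of m6A and expression was weighed against 3 explanations. It was not carried by strongly changed genes, since rho was -0.121 without genes with an absolute expression change of 1 or more, nor by ribosome genes, since it was -0.134 without them. If the authors' fold was taken over these input libraries, their noise would give a negative covariance equal in size to the mean squared SE. The observed covariance was 4.64 times that in genes of at least 10 FPKM. Under this assumption, which the sources used here do not settle, that is more than such noise alone would give. It is just short of the bound of 5 set beforehand, so a contribution of shared input remains open. A difference in floral organs between the genotypes was not among the 3 explanations and was not tested, so it remains open too. An effect of methylation on transcript level is consistent with the sign but was not tested here.

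HSP23.5 was among the strongest increases, and 7 genes of the mitochondrial stress response that had been seen to rise, among them UPOX and UGT74E2, had a median log2 change of 3.19. Among 10 tested members of that response not looked at before, 60% rose and 1 fell, or 5 and 1 after median centring. Of all 19505 tested genes 8016 rose. The median log2 change of the 10 members was 0.376 (camera p = 0.0476, or p = 0.135 with an estimated correlation). Their largest risers were ANAC013, from 6.16 ± 0.685 to 25.4 ± 0.617 FPKM, and AOX1A, from 18.9 ± 0.292 to 53.5 ± 1.17 FPKM. CYP81D8 fell by 0.58, and OM66, GSTU24 and TIM17-1 did not pass the test. Cytosolic heat-shock genes rose in 8 of 11 tested members with a median of 1.19 (camera p = 0.000131; p = 0.016 with an estimated correlation), HSP70 going from 17.1 ± 0.422 to 112 ± 1.98 FPKM. Either a mitochondrial stress response or a general heat-shock response could account for part of the pattern, and the data do not rank them. MBF1C was at 17.65 FPKM in Col-0 replicate 2 and at 1.37 and 1.45 in the other Col-0 libraries.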
